A study of Homo sapiens with 5 samples.

How the data were processed

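Ribosome-protected fragments of HAP1 cells were measured in 5 libraries, 2 from wild-type cells and 3 from ZCCHC4 knockout cells, grouped by the genotype and titles in the labels. Per the labels' protocols, lysates prepared with cycloheximide were digested with RNase I, monosomes were isolated on sucrose gradients, and fragments of 28 to 32 nt were cut from a gel and cloned with adapters carrying random bases. The labels' molecule field names polyA RNA, whereas the protocol describes footprints of ribosomes, and the values were read as footprint counts. Per the submitters' processing notes, Bowtie (version not given) and the hg38 build were used. The counting tool, the annotation, adapter trimming, the use of the random bases to remove duplicates, removal of rRNA reads, strand and the treatment of reads mapping to several places are not given in the sources used here. Reads of paralogs, pseudogenes, overlapping and antisense genes could therefore have been split or shared, and genes with near-identical copies are uncertain. With cycloheximide and a single count per transcript, the values can include footprints that gathered near start codons or in untranslated regions, which the table does not separate.

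The deposited count table gave whole-number counts per transcript and gene symbol, not normalized, per the file headers and the values. Its header line was shifted by 1 cell against the values, and columns were assigned by their names after that shift. It held 13638 rows with 13597 symbols, of which 38 occurred more than once. No row lacked a gene name and none was mitochondrially encoded. Transcript identifiers were matched to GENCODE release 29 on GRCh38, which placed 13533 rows and left 105 unmatched, and 13525 were protein coding. Older gene symbols are printed as the table gives them. Genes without a row, among them the mitochondrially encoded subunits of oxidative phosphorylation, were not analysed here.

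Library totals were 5302160 and 4887380 counts in wild type and 29191146, 16940732 and 31557573 in the knockout. The 10 most abundant genes took 3.99% and 3.98% of the wild-type counts and 6.05%, 6.51% and 6.09% of the knockout counts. TMM factors were 1.09 and 1.10 in wild type and 0.935, 0.953 and 0.936 in the knockout. A gene with no count is limited to 3 counts, or 0.517 and 0.560 CPM in the wild-type libraries and at most 0.186 CPM in the knockout libraries. Limits and exact 95% binomial intervals of ratios cover counting error only, since footprints amplified by PCR are not independent molecules.

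Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr with a minimum count of 10, glmQLFit and glmQLFTest with genotype as the only term, Benjamini-Hochberg adjusted p under 0.05). The filter kept 11205 rows, each taken as a gene, and left out 2433. CPM are TMM-scaled, and the SE of a log2 fold change is approximate, its size divided by the square root of the F statistic. Log2 fold changes are knockout over wild type. Libraries were compared in pairs by a chi-square test over genes with at least 20 counts in the pair. The wild-type libraries differed slightly by this test (a statistic of 11664 on 10240 degrees of freedom). They were kept as 2 replicates because the labels give them as such. With PCR-amplified reads, repeat sequencing or preparation of a single sample could also differ this much, so the test does not show that they are independent.

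Before the data were examined, 33 gene lists, the tests, the alternatives and the rule for named genes were written down. A list with at least 5 tested members was tested by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the 32 lists tested, and again with an estimated correlation. The version with an estimated correlation also uses the few residual degrees of freedom of 5 libraries, so it passes lists less readily whatever their correlation. The list of mitochondrially encoded oxidative phosphorylation subunits had no row in the table and was not tested. Directional fry tests whether the genes of a list move, on balance, in a single direction and mixed fry whether they change in either direction; neither compares a list with other genes. Medians were also ranked among 10000 random lists matched on level in 20 bins. The genes named were ZCCHC4, the 12 largest rises and 12 largest falls among passing genes with an average log2 CPM of at least 3 and no overlap between the genotypes, and the members of each list with the smallest adjusted p, up to 3 for a list past camera and up to 2 for the others. Some genes that this rule selects are not reported here. Stretches of chromosomes 8 and 16 and gene families were chosen after the values were seen, as is said beside them.

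The procedure was tested on simulated counts for the 11205 genes with 200 changed genes. It recovered 14% of 50 genes changed 1.25-fold, 64% at 1.5-fold, 86% at 2-fold and 96% at 4-fold, and called 9 of 11005 unchanged genes, or 6.47% of 139 calls. A simulated shift of 1 list was recovered and no other list was called. The simulated genes were drawn independently, whereas the estimated correlation within a list reached 0.488 in the data, for glycolysis. The simulation therefore does not show how often camera with the preset correlation calls correlated lists falsely.

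Alternatives were RLE, upper quartile and library-total scaling, no filter, a mean count of at least 50, a robust fit, the replicate number as a block, leaving out each library, leaving out the 50 most abundant genes, DESeq2 1.42.0, limma-voom, other thresholds, and fry or ranks for the lists. Alternatives added after seeing the data were summing the near-identical libraries, thinning the knockout counts to the wild-type total, leaving out chromosome 8 below 50 Mb, and counting genes changed at least 2-fold under each alternative. Coding length and GC content of the annotated transcripts, known for 99.6% of tested genes, entered spline fits with 4 degrees of freedom. Where level entered a fit or the matching of random lists, it was the average over all 5 libraries, knockout included. Adjusting for it can therefore remove part of a difference between the genotypes, and the random lists could draw members of the list itself.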

Results

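Ribosome footprints were counted in 5 libraries of HAP1 cells, a human line derived from chronic myeloid leukaemia cells that carries close to a single set of chromosomes. The wild-type group held 2 libraries and the ZCCHC4 knockout group held 3. ZCCHC4 is the enzyme that the series names as the writer of N6-methyladenosine (m6A) on 28S ribosomal RNA. A footprint is the stretch of mRNA that a ribosome shields from nuclease, so a gene's count follows both the amount of its mRNA and its occupancy by ribosomes. No RNA-seq libraries were used here, and the contributions of mRNA level and translation were not separated. The wild-type totals were 5302160 and 4887380 counts, and the knockout totals were 29191146, 16940732 and 31557573 counts, so depth and genotype moved together. One count corresponded to 0.172 and 0.187 CPM, counts scaled to a common library total, in the wild-type libraries and to between 0.0339 and 0.0619 CPM in the knockout libraries.

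Libraries of a genotype resembled each other far more than libraries across genotypes. The wild-type pair differed by little more than sampling noise, with a chi-square per degree of freedom of 1.14 and a variation beyond counting error of 1.43%. Knockout replicates 1 and 3 gave 2.97 and 2.88%. Knockout replicate 2 stood apart from these, at 27.7 and 13.5% against replicate 1 and at 24.6 and 12.3% against replicate 3. Pairs across genotypes gave between 89.7 and 106, with a variation of 45.8% to 47.3%. The labels do not say whether the libraries came from separate cultures or clones, so p-values measure the spread between these libraries, which may be technical.

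The targeted gene was examined first. ZCCHC4 (ENST00000302874, ENSG00000168228, GRCh38 chromosome 4, 25312786 to 25370383, plus strand, a protein-coding transcript with 13 exons) fell 3.54-fold in the knockout libraries. Its level was 14.6 ± 1.97 CPM in wild type (SD, n = 2) and 4.08 ± 0.81 CPM in the knockout (SD, n = 3), or 27.8% of the wild-type level. The log2 fold change was -1.82 ± 0.20 (SE), with an edgeR adjusted p of 7.27e-05. Raw counts were 93 and 71 in the wild-type libraries and 105, 55 and 147 in the knockout libraries, and all 3 knockout libraries lay below both wild-type libraries at 3.85, 3.41 and 4.98 CPM. These levels were above the limit that a count of 0 would allow there, which was at most 0.186 CPM. The table gives a single count per transcript, so the position of the remaining footprints along ZCCHC4 was not analysed here.

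**Figure D1:**
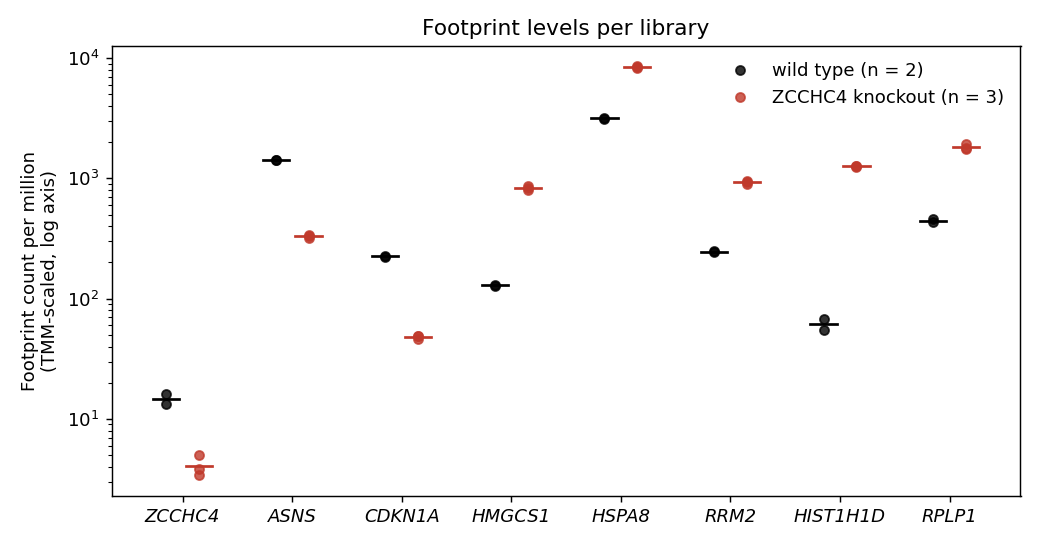
TMM-scaled footprint CPM (log axis) of 8 genes in each library, with wild type in black (n = 2) and ZCCHC4 knockout in red (n = 3). Points are libraries and lines are group means; ZCCHC4, ASNS and CDKN1A lay lower and HMGCS1, HSPA8, RRM2, HIST1H1D and RPLP1 higher in all 3 knockout libraries than in both wild-type libraries.

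Comparing the genotypes asks which genes hold a larger or smaller share of the footprints in the libraries labelled as knockout of the 28S rRNA methyltransferase. Higher and lower are relative to the other genes, because the counts were scaled between libraries. A rise or fall in translation shared by all genes would not be seen. Of 11205 genes tested, 6721 (60.0%) changed, with 3380 higher and 3341 lower in the knockout libraries, and 4484 did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At least a 2-fold change was found for 2595 of the changed genes, of which 1124 rose and 1471 fell, and at least a 4-fold change for 855, of which 261 rose and 594 fell. The median size of the change among the passing genes was 1.76-fold. In 8557 genes (76.4%) the libraries of the genotypes did not overlap, where 20% would apply if the 5 libraries were exchangeable. Because libraries of a genotype were so alike, any difference of culture or preparation that goes with genotype could also separate them. With library totals in place of TMM scaling, the split was 2391 higher and 4564 lower, and the median log2 fold change of all genes moved from 0.02 to -0.20. The excess of falls among 2-fold changes depended on settings, with 826 rises and 832 falls at a mean count of at least 50 and 763 rises and 1925 falls with library totals.

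**Figure D2:**
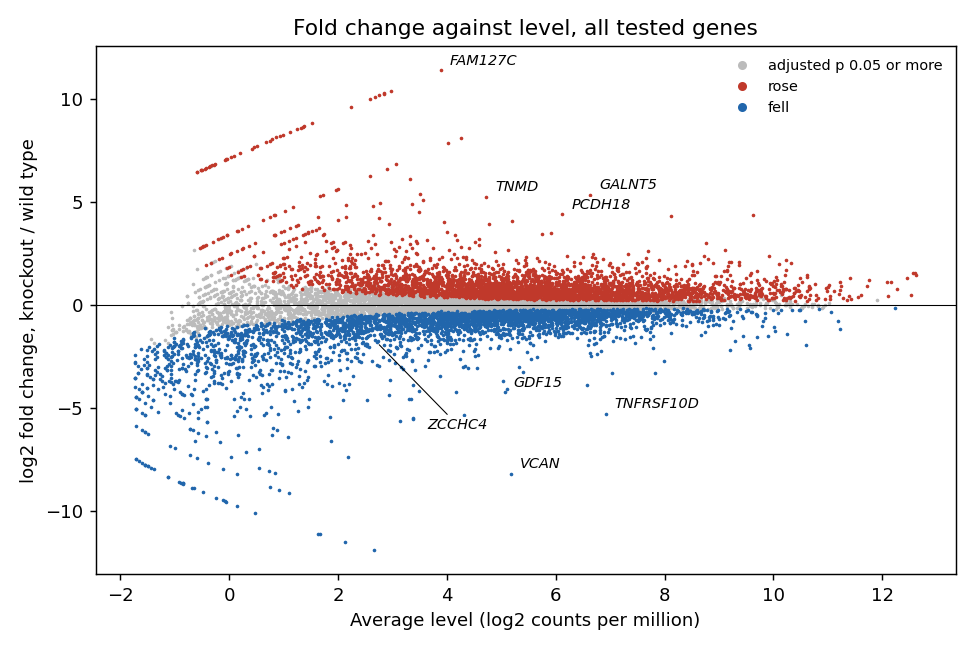
Log2 fold change of knockout over wild type (y axis) against the average level in log2 CPM (x axis) for the 11205 tested genes, with the 3380 that rose in red, the 3341 that fell in blue and the rest in grey. The straight streaks at the edges are genes with few or no counts in a genotype, whose fitted fold changes are not bounds.

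The largest rises among genes with an average log2 CPM of at least 3 were in genes with low levels in wild type. Ranking by fold change favours such genes, and some reached that average through the knockout libraries alone. GALNT5, a transferase that starts mucin-type O-glycosylation (GRCh38 chromosome 2, 157257598 to 157314211), rose from 3.77 ± 0.211 to 153 ± 1.10 CPM (SD, n = 2 and n = 3), a log2 fold change of 5.35 ± 0.13 (SE). PCDH18, a protocadherin of cell adhesion, rose from 5.02 ± 0.0273 to 105 ± 2.57 CPM (4.38 ± 0.13). TNMD, a membrane glycoprotein of tendon, rose from 0.984 to 37.3 CPM (5.23 ± 0.22). GADL1, an amino acid decarboxylase, MICALCL, the thiamine transporter SLC19A3 and the axon guidance factor SEMA3A rose by 5.35, 5.09, 4.87 and 4.51 on the log2 scale. FAM127C, which has near-identical neighbouring copies and is uncertain for that reason, had no count in either wild-type library and was at least 74.3-fold higher in the knockout, against a floor of 3 counts over the wild-type group. The rest of this group had only 1 or 2 wild-type counts in all. MARC1, a mitochondrial reductase, was higher by a ratio of 290.5-fold (95% interval 52.1 to 11479), MYO5C, an unconventional myosin, 247-fold (95% interval 44.3 to 9758), and TUBB1, a beta-tubulin of platelets, 115-fold (95% interval 20.6 to 4547), each with 1 wild-type count. MYOF, a membrane repair protein, was higher by a ratio of 71.5-fold (95% interval 19.8 to 592) with 2 wild-type counts, and these intervals and floors cover counting error only.

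The largest falls among genes with an average log2 CPM of at least 3 were in genes of varied function. VCAN, a large proteoglycan of the extracellular matrix (GRCh38 chromosome 5, 83471465 to 83582303), fell from 110.5 ± 4.98 to 0.334 ± 0.185 CPM (SD, n = 2 and n = 3), a log2 fold change of -8.20 ± 0.19 (SE). TNFRSF10D, a decoy receptor for the death ligand TRAIL (GRCh38 chromosome 8, 23135588 to 23164030), fell from 312 ± 9.95 to 7.93 ± 0.414 CPM (-5.30 ± 0.09). PDGFRA, a receptor tyrosine kinase, fell by 4.18 on the log2 scale, and the cell surface proteins TSPAN7 and SDK1 had log2 fold changes of -4.25 and -4.60. FSTL4, a follistatin-like protein, was at -5.56. The histone variant gene H2AFY2 was at -5.65, the retinoic acid binding protein CRABP1 at -4.60, and AKNA at -4.12. GDF15, a stress-induced cytokine, fell from 93.7 to 4.98 CPM (-4.25 ± 0.16), and EGR3, an immediate early transcription factor, from 39.3 to 0.861 CPM (-5.52 ± 0.22). TNFRSF10D and EGR3 lie on chromosome 8 below 50 Mb, a stretch whose genes had a median log2 fold change of -0.90. Of the 97 genes that the naming rule selects, 58 rose and 39 fell.

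Genes of the amino acid stress response were lower in the knockout libraries. Of 35 tested targets of ATF4, the transcription factor of the integrated stress response, 27 fell, 5 rose and 3 did not pass, with a median log2 fold change of -0.96 (1.95-fold lower). TRIB3, a pseudokinase induced by ATF4, fell from 234 ± 3.38 to 15.7 ± 2.05 CPM (-3.90 ± 0.11; SE, n = 2 and n = 3), and ASNS, asparagine synthetase, from 1423 ± 0.282 to 329.8 ± 11.7 CPM (-2.11 ± 0.06). The list passed camera at an adjusted p of 3.61e-12, with an adjusted p = 0.271 with an estimated correlation. The cytosolic aminoacyl-tRNA synthetases, which load tRNAs with amino acids, moved the same way, with 15 of 21 falling, 5 rising and a median of -0.71 (camera adjusted p = 4.44e-09, and adjusted p = 0.087 with an estimated correlation). WARS fell from 1127 to 244 CPM (-2.21 ± 0.06), IARS from 2812 to 728 CPM (-1.95 ± 0.05) and YARS from 1142 to 396 CPM (-1.53 ± 0.06). Solute carriers for amino acids did not pass as a list (4 rose and 8 fell of 21, median -0.15, camera adjusted p = 0.148), although the glycine transporter SLC6A9 fell by 2.51 and the cystine transporter SLC7A11 by 1.91 on the log2 scale. The unfolded protein response list did not pass either (7 rose and 8 fell of 23, or 7 and 9 adjusted over the list alone, camera adjusted p = 0.179), with falls in the degradation factors HERPUD1 (-1.87 ± 0.10) and SEL1L (-1.56 ± 0.07).

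Targets of p53 and immediate early genes were also lower. Of 25 p53 targets, 18 fell, 2 rose and 5 did not pass, with a median of -0.84 (1.79-fold lower). CDKN1A, the cyclin-dependent kinase inhibitor p21, fell from 226 ± 3.75 to 48.1 ± 1.36 CPM (-2.23 ± 0.08; SE, n = 2 and n = 3), and MDM2, the ubiquitin ligase of p53, from 1359.5 to 353 CPM (-1.95 ± 0.07). The death receptor gene TNFRSF10B, on chromosome 8 below 50 Mb, was at -1.66 ± 0.07. Of 28 MYC and immediate early genes, 20 fell, 4 rose and 4 did not pass, with a median of -1.27. MYC itself, named after its value was seen, was among the rises at 0.28 ± 0.07 (adjusted p = 0.00736), a rise little larger in size than the shift of -0.22 that library totals give the median of all genes. The AP-1 subunits FOSL1 and JUN fell from 111 to 19.3 CPM (-2.53 ± 0.09) and from 32.5 to 6.64 CPM (-2.30 ± 0.14). Camera gave adjusted p values of 7.67e-09 for the p53 targets and 1.19e-07 for the immediate early genes, with adjusted p = 0.16 and adjusted p = 0.303 with an estimated correlation.

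Sterol synthesis genes and genes of the heat shock list were higher in the knockout libraries. Of 25 cholesterol synthesis genes, 23 rose (24 adjusted over the list alone), 1 fell and 1 did not pass, with a median log2 fold change of 1.63 (3.09-fold higher). HMGCS1, which makes the HMG-CoA used for sterols, rose from 129 ± 1.79 to 826 ± 32.7 CPM (2.67 ± 0.07; SE, n = 2 and n = 3). The methylsterol oxidase gene MSMO1 rose from 50.0 to 305 CPM (2.61 ± 0.11). Of 20 genes of the heat shock list, mostly cytosolic chaperones, 17 rose, 1 fell and 2 did not pass, with a median of 1.10. The cytosolic chaperone genes HSP90AB1 and HSPA8 and the mitochondrial co-chaperone gene HSPE1 had log2 fold changes of 1.54 ± 0.05, 1.42 ± 0.05 and 2.03 ± 0.09. The member that fell, HSF1 (-0.52 ± 0.13), encodes a transcription factor of heat shock genes and is named here after its value was seen. After a fit on coding length, GC content and level the list's median was 0.69. Camera gave adjusted p values of 3.59e-21 for sterol synthesis and 2.68e-10 for the heat shock list, with adjusted p = 0.087 and adjusted p = 0.196 with an estimated correlation.

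DNA replication and histone genes were higher in the knockout libraries. Of 35 DNA replication and G1/S genes, 27 rose, 2 fell and 6 did not pass, with a median of 0.83 (1.78-fold higher). RRM2, a subunit of ribonucleotide reductase, rose from 246 ± 2.47 to 928 ± 30.1 CPM (1.92 ± 0.07; SE, n = 2 and n = 3), and the replicative helicase subunits MCM6 and MCM4 had log2 fold changes of 1.13 ± 0.06 and 1.09 ± 0.06. Of 43 replication-dependent histone genes, 39 rose (40 adjusted over the list alone), 1 fell and 3 did not pass, with a median of 1.45. HIST1H1D, a linker histone, rose from 61.2 ± 9.51 to 1257 ± 8.48 CPM (4.36 ± 0.10), and HIST1H3H and HIST1H2BO had log2 fold changes of 2.98 ± 0.11 and 1.93 ± 0.08. Mitosis genes passed more narrowly, with 18 rising and 5 falling of 32 (19 and 6 adjusted over the list alone) and a median of 0.41. ANLN, MAD2L1 and KIF20A, which act in cytokinesis and the spindle checkpoint, were at 1.96 ± 0.11, 1.05 ± 0.07 and 0.91 ± 0.08. Camera gave adjusted p values of 1.20e-09, 1.14e-25 and 0.0269 for replication, histone and mitosis genes, with adjusted p = 0.087, adjusted p = 0.16 and adjusted p = 0.65 with an estimated correlation. Histone genes have near-identical copies, and their single values are uncertain where counting could split reads. The mitosis call was lost without wild-type replicate 1 (adjusted p = 0.0539), without knockout replicate 1 (0.0560), with library totals (0.0984, median 0.19), at a mean count of at least 50 (0.0940) and with the near-identical libraries summed (0.0743), and its median was 0.10 after a fit on coding length, GC content and level. Among random lists matched on level, the unadjusted mitosis median lay at percentile 92.7.

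Ribosomal protein genes were slightly higher, in a direction that did not hold after adjustment for coding length, GC content and level. Of 40 genes for the cytosolic large subunit, 25 rose, 4 fell and 11 did not pass, with a median of 0.31 (1.24-fold higher). RPLP1, a stalk protein, rose from 445 ± 14.5 to 1824 ± 96.4 CPM (2.04 ± 0.07; SE, n = 2 and n = 3), and RPL7A and RPL23A had log2 fold changes of 1.44 ± 0.06 and 1.31 ± 0.06. Of 25 small-subunit genes, 14 rose (15 adjusted over the list alone), 2 fell and 9 did not pass, with a median of 0.29, and RPS29, RPS4X and RPS13 were at 1.06 ± 0.07, 0.72 ± 0.05 and 0.64 ± 0.06. Camera gave adjusted p values of 4.43e-04 and 0.0458 for the large and the small subunit, with adjusted p = 0.303 and adjusted p = 0.281 with an estimated correlation. After a spline fit on those properties the medians turned to -0.16 and -0.27, and among 10000 random lists matched on level alone the unadjusted medians lay at percentiles 35.7 and 32.4. The level used in both includes the knockout values, so both can also hide part of a rise. Ribosomal protein genes share sequence with many pseudogenes, so single values are uncertain. The small-subunit call was lost in 12 alternatives, among them each other scaling (adjusted p = 0.0505 with RLE, 0.0812 with the upper quartile and 0.213 with library totals, median 0.07) and leaving out wild-type replicate 1 (0.0585) or 2 (0.0980) or knockout replicate 1 (0.0712) or 3 (0.0653).

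Other parts of the translation apparatus moved in both directions and did not pass camera. Directional fry, which makes no comparison with other genes, passed for 26 of the 32 lists. Among the lists given here, it did not pass for initiation factors (adjusted p = 0.12) and the m6A list (adjusted p = 0.185). Mitochondrial ribosomal proteins rose in 32 and fell in 12 of 70 cases (median 0.18, adjusted p = 0.101), with MRPS21 at 1.16 ± 0.09 and MRPL24 at -1.13 ± 0.08. Initiation factors rose in 16 and fell in 7 of 38 cases (adjusted p = 0.339), and EIF1, which takes part in start codon selection, fell from 1508 to 709 CPM (-1.09 ± 0.10), while the initiation factor gene EIF3G was at -0.68 ± 0.07. Elongation and termination factors gave 3 rises and 1 fall among 16 (adjusted p = 0.432), with EIF5A at 0.68 ± 0.07 and the diphthamide enzyme DPH2 at 0.85 ± 0.15. Large-subunit assembly factors, which include CEBPZ (1.35 ± 0.12) and NOP2 (1.03 ± 0.09), gave 23 rises and 11 falls among 51 (adjusted p = 0.101). Small-subunit assembly factors, which include EMG1 (1.67 ± 0.11) and BYSL (1.27 ± 0.10), gave 19 rises and 9 falls among 44 (adjusted p = 0.147). The rRNA modification list, which holds ZCCHC4 itself, gave 10 rises and 6 falls among 21 (adjusted p = 0.339). Writers, readers and erasers of m6A, again with ZCCHC4 among them, gave 7 rises and 5 falls among 23 (adjusted p = 0.557), with the m6A readers HNRNPA2B1 at 1.19 ± 0.08 and IGF2BP2 at -1.20 ± 0.09. Ribosome quality control genes gave 6 rises (5 adjusted over the list alone) and 5 falls among 23 (median -0.03, adjusted p = 0.558 in the upward direction, so the median and the test differed in sign). PELO, which rescues stalled ribosomes, rose by 1.46 ± 0.12, and TCF25, on chromosome 16 from 80 Mb, by 1.48 ± 0.10. Proteasome subunits gave 14 rises (17 adjusted over the list alone) and 4 falls among 30 (adjusted p = 0.138), with PSMA3 at 0.72 ± 0.07 and PSME3 at 0.82 ± 0.08. Without knockout replicate 2, the lists of large-subunit assembly factors, proteasome subunits and NRF2 targets passed, and 16 lists passed in place of 13.

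Genes of glycolysis and oxidative phosphorylation were higher before adjustment for coding length, GC content and level. Of 21 glycolysis genes, 12 rose, 2 fell and 7 did not pass, with a median of 0.70 (1.62-fold higher). PGK1, PKM and LDHA, enzymes of the lower part of the pathway, rose by 1.12 ± 0.07, 1.09 ± 0.07 and 0.95 ± 0.06. Of 67 nuclear-encoded oxidative phosphorylation genes, 35 rose, 12 fell and 20 did not pass, with a median of 0.30. COX6B1 and COX7C of cytochrome c oxidase were at 1.43 ± 0.07 and 1.40 ± 0.07, and ATP5G3 of ATP synthase at 1.31 ± 0.07. Camera gave adjusted p values of 4.43e-04 for glycolysis and 0.00443 for oxidative phosphorylation, with adjusted p = 0.52 and adjusted p = 0.16 with an estimated correlation. After a fit on those properties the median was 0.20 for glycolysis and turned to -0.11 for oxidative phosphorylation. Among random lists matched on level, the unadjusted medians lay at percentile 99.8 for glycolysis and 85.4 for oxidative phosphorylation. The glycolysis call was lost without the 50 most abundant genes (adjusted p = 0.0987, median 0.16). Hypoxia response genes gave 6 rises and 4 falls among 18 (adjusted p = 0.699), with the glucose transporter SLC2A1 at 1.85 ± 0.18 and the growth factor VEGFA at -1.69 ± 0.12. NRF2 targets gave 11 rises (12 adjusted over the list alone) and 2 falls among 20 (adjusted p = 0.0826), with TALDO1 of the pentose phosphate pathway at 0.91 ± 0.07. Their median lay at percentile 99.8 of the matched lists, although camera did not call them. Autophagy and lysosome genes gave 10 rises and 5 falls among 27 (adjusted p = 0.577), with the lysosomal galactosidase GLA at 1.17 ± 0.09 and the autophagy protein WIPI1 at -3.92 ± 0.14.

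Lists of markers of other cell types and of interferon-stimulated genes did not pass camera, which compares a list with other genes. Directional fry, which does not, passed for matrix and mesenchymal (adjusted p = 0.0421), epithelial (0.00514), haematopoietic (0.0367) and interferon-stimulated genes (0.00424) and not for neural markers (0.0629). Among random lists matched on level, the median of the matrix markers lay at percentile 0.48 and that of the interferon-stimulated genes at percentile 99.8. Extracellular matrix and mesenchymal markers gave 8 rises and 11 falls among 21 (camera adjusted p = 0.406). VIM, an intermediate filament protein, rose from 132 ± 12.2 to 511 ± 18.8 CPM (1.95 ± 0.08; SE, n = 2 and n = 3), and LOXL2, a lysyl oxidase encoded on chromosome 8 below 50 Mb, was at -2.42 ± 0.15. Epithelial markers gave 1 rise and 3 falls among 8 (adjusted p = 0.0903), and the epithelial splicing regulator ESRP1 and the tight junction gene TJP3 were at -3.05 ± 0.11 and -2.58 ± 0.32. Haematopoietic and leukaemic markers gave 1 rise and 4 falls among 9 (adjusted p = 0.339), with the receptor tyrosine kinase gene KIT at -2.80 ± 0.21 and the transcription factor gene GATA2 at 0.95 ± 0.12. Neural markers gave 5 rises and 7 falls among 15 (6 and 8 adjusted over the list alone, adjusted p = 0.352), with TUBB3, also on chromosome 16 from 80 Mb, at 2.24 ± 0.12 and DPYSL3 at -2.57 ± 0.15. Interferon-stimulated genes gave 10 rises and 5 falls among 24 (adjusted p = 0.339), with the antiviral gene BST2 at 2.23 ± 0.09 and HLA-B, which shares sequence with other HLA genes, at -1.46 ± 0.11.

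In total 13 of 32 tested lists passed camera with a preset correlation of 0.01, 9 upward and 4 downward. None of the 13 passed with an estimated correlation, where adjusted p ranged from 0.0870 to 0.650 and 7 of the 32 lists had an unadjusted p under 0.05. These losses need not come from correlation. The tRNA synthetases had an estimated correlation of -0.011, below the preset 0.01, yet their unadjusted camera p went from 8.32e-10 to 0.0067. Other lists had higher estimates, up to 0.488 for glycolysis. Counts of members adjusted over the list alone equalled those over all genes in 23 lists. In 4 lists a member had no count in 1 genotype, and setting these members to their bounds left the medians as given.

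**Figure D3:**
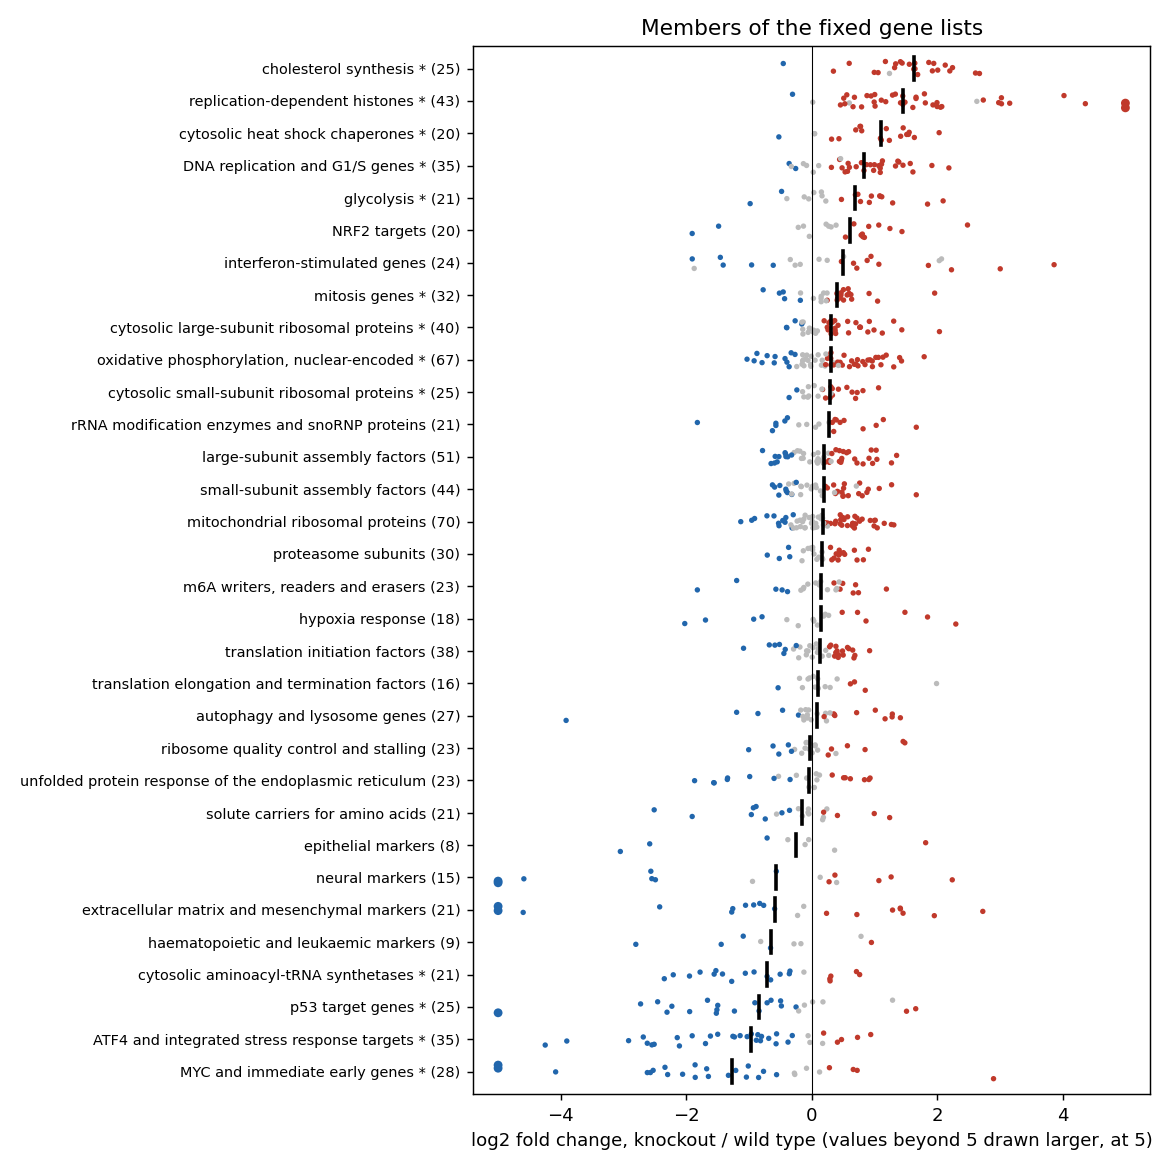
Log2 fold change of knockout over wild type (x axis) for each tested member of the 32 gene lists, ordered by median (black bars), with members that rose in red, fell in blue and did not pass in grey. Numbers in parentheses are tested members, and asterisks mark the 13 lists with a camera adjusted p under 0.05, of which none passed with an estimated correlation.

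Genes on chromosome 8 below 50 Mb, a stretch chosen after its values were seen, were lower together. Of the 143 tested genes there (GRCh38, from the first transcript's start at 232137 to the last transcript's end at 48064708), 104 fell, 9 rose and 30 did not pass. Their median log2 fold change was -0.90 (interquartile range -1.29 to -0.28), or 1.86-fold lower, and 126 of them (88.1%) lay below the median of all genes. The median was -0.89, -0.88 and -0.88 in knockout replicates 1, 2 and 3. The other 245 genes of the chromosome had a median of 0.10, with 86 higher and 70 lower. Under the other scalings the median of the stretch lay between -1.12 and -0.91. TNFRSF10D, TNFRSF10B, EGR3 and LOXL2 lie in this stretch and fell, while MCM4, near its end at 47960898 to 47978160, rose.

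**Figure D4:**
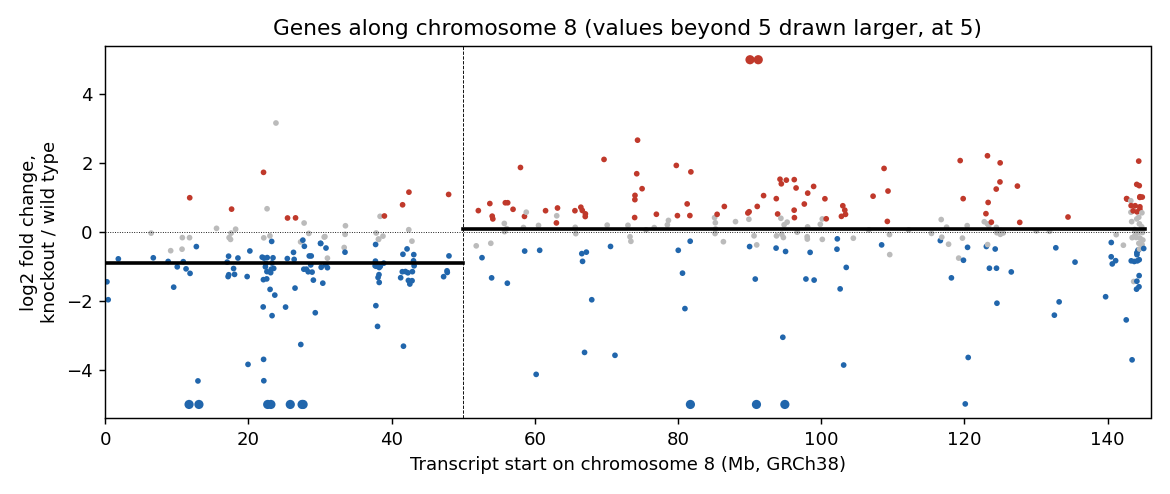
Log2 fold change of knockout over wild type (y axis) for tested genes along chromosome 8 (x axis, Mb on GRCh38), with genes that rose in red, fell in blue and did not pass in grey. Black lines are the medians of -0.90 for the 143 genes below 50 Mb (dashed line) and 0.10 for the other 245.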

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

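Summing the near-identical libraries, thinning, leaving out chromosome 8 below 50 Mb and counting 2-fold changes under each alternative were chosen after seeing the data. ZCCHC4 kept its direction and passed in all 18 alternatives, with log2 fold changes from -2.04 to -1.68 and adjusted p of up to 0.00396. The named genes kept direction and call in 1713 of 1713 combinations of gene and alternative, which their selection for large or firm changes favours and which does not extend to other genes. Changed genes numbered 4698 to 8176 with a library left out, 4604 with the near-identical libraries summed (4579 of them among the 6721, or 68.1% of those; the lone wild-type library is then assumed to vary like the knockout), 6407 with the knockout thinned, 6231 with DESeq2, 6432 with limma-voom and 7056 without a filter. Requiring at least a 2-fold change left 2595, by construction. These 2595 became 1658 with a mean count of at least 50, where fewer genes were tested, and 2262 to 2645 with a library left out. Lists past camera numbered 11 to 16 with a library left out, 0 with an estimated correlation, 26 by directional fry and 32 by mixed fry, which ask other questions of a list. Of 671 combinations of list and alternative, 617 kept their side of the threshold and direction, 31 lost the call, 21 gained it and 2 reversed. The reversals, of the median or the test, came with a mean count of at least 50, for matrix and mesenchymal markers (median -0.30) and neural markers (median 0.25), neither of which passed in the main test; the cause was not tested. The labels do not say that replicate numbers mark a shared day or batch, and deviations of same-numbered libraries correlated at -0.05, in effect a single value because the deviations of 2 wild-type libraries mirror each other, so pairing was not shown. With the number as a block, 6094 genes passed (3068 higher, 3026 lower), with 2569 changed at least 2-fold and 12 lists, the small-subunit ribosomal list losing its call (adjusted p = 0.0788). That list also lost its call at a mean count of at least 50 (0.147), without the 50 most abundant genes (0.0987), with the near-identical libraries summed (0.135) and without chromosome 8 below 50 Mb (0.0558). Without mitochondrially encoded genes nothing could be run, as the table held none. In simulated counts of this depth, with 200 changed genes and independent replicates, 64% of 1.5-fold changes were recovered. That share need not carry over to these data, in which 60.0% of genes passed and some libraries were near-identical.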

Other observations

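Gene families, stretches of chromosomes and the tests of coding length with GC content and of copy number were chosen after the values were seen. Among 167 families of at least 8 tested members sharing a symbol stem, 7 passed camera, and none did with an estimated correlation (adjusted p of at least 0.991, with an unadjusted p under 0.05 for 4 families). Besides histone and large-subunit ribosomal protein genes, which rose, these were families that fell. No family median was adjusted for coding length, with which the fold changes of all genes had a Spearman correlation of -0.16. All 9 tested DOCK genes fell, with a median log2 fold change of -1.78 (camera adjusted p = 0.00170), and DOCK3 reached -2.26. Of 9 numbered integrin alpha genes, which encode adhesion receptors, 8 fell and none rose (median -1.28, adjusted p = 0.00299), with ITGA9 at -2.31 and ITGA5 at -1.33. VPS genes of vesicle sorting fell in 18 of 31 cases and rose in 4 (median -0.58, adjusted p = 0.0193), and septin genes fell in 7 of 11 with no rise (median -0.47, adjusted p = 0.0468). TNFRSF genes fell in 5 of 10 cases and rose in 1 (median -1.11, adjusted p = 0.00125), and the 4 TRAIL receptor genes TNFRSF10A to TNFRSF10D, which neighbour each other on chromosome 8 below 50 Mb, all fell. Intraflagellar transport genes fell in 10 of 13 cases, at an adjusted p of 0.0618. On chromosome 16 from 80 Mb, 37 of 67 genes rose and 8 fell, with a median of 0.60 (1.52-fold higher) against -0.04 for the rest of that chromosome, and TCF25 and TUBB3 lie there.

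Of the tested genes, 60.0% changed between the genotypes. Whether counting near-identical libraries as separate replicates accounts for these calls could not be decided. The fit with those libraries summed takes its spread from the knockout libraries and assumes that the lone wild-type library varies like them. The labels do not say that the knockout libraries came from separate cultures or clones, so that spread may itself be technical. With the knockout counts thinned to the wild-type total, 6407 genes passed, so the larger number of knockout counts does not account for most calls. The median size of the log2 fold changes was 0.81 before and 0.81 after thinning, but random thinning keeps expected fold changes. Thinning therefore cannot test differences in preparation or duplication that go with depth. Splines of coding length and GC content accounted for a share of 0.0368 of the variance of the fold changes, and 0.163 with level added, which leaves most of it to other sources. Differences of culture, clone or library preparation that go with genotype stay open, as the labels give no batch, and the effect of losing ZCCHC4 stays a hypothesis among them.

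Genes of chromosome 8 below 50 Mb, which covers the short arm, were lower together in the knockout. Coding length, GC content and level do not account for this, as the median was -0.96 after a fit on them, and ordinary spread along the genome does not reach it, since the lowest stretch of 143 neighbouring genes on other chromosomes had a median of -0.31. A candidate explanation is fewer copies of this stretch in the knockout cells. It predicts a median near -1 there and near 0 on the rest of the chromosome, and the medians were -0.90 and 0.10. That prediction was written after the values were seen, so the match is no independent test of it. Unless the knockout cells held more copies of the other chromosomes, this explanation would need more than a single copy in the wild-type cells. The titles of the libraries of both genotypes say haploid, and ploidy and DNA copy number were not measured here. Whether such a difference arose by clonal selection or in culture was not tested.

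ATF4 targets and tRNA synthetases were lower, and sterol, replication, histone and heat shock genes higher, in the knockout. As lists they passed camera with the preset correlation, and none did with an estimated correlation, a version that also has few degrees of freedom with 5 libraries. Coding length, GC content and level do not account for these shifts, because each of the 6 medians kept at least 0.626 of its size after a fit on them, the least being that of the heat shock list, whereas of the other lists past camera both ribosomal lists (-0.16 and -0.27) and oxidative phosphorylation (-0.11) changed sign, glycolysis (0.20) and mitosis (0.10) shrank, and p53 targets (-1.08) and immediate early genes (-1.24) kept nearly all of their size or more. With the knockout counts thinned, each of the 6 medians kept at least 0.965 of its size. Random thinning keeps expected fold changes, so this outcome was nearly bound to occur and does not test causes that go with depth. Because p53 and immediate early genes were lower too, a difference in the state of the cultures at harvest, such as density, nutrients or growth rate, may stand behind the lists as well as the loss of ZCCHC4. Neither was tested, and reads shared between histone copies stay open for single histone genes.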
